A study of Streptomyces venezuelae with 12 samples.

How the data were processed

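RNA from 12 samples of Streptomyces venezuelae was sequenced, 2 libraries in each of 6 groups that combine a medium (YP or YPG) with a time. Growth, lysis, rRNA depletion with a Ribo-Zero kit and library construction with a directional NEBNext kit are known from the labels' protocols. Bowtie2, SAMtools, HTSeq and DESeq2 were used, per the submitters' processing notes; their versions, the genome build and the annotation are not given in the sources used here. The deposited table holds 1 normalised signal per ID and library, which the authors made by dividing read counts by 1 size factor per library, as the file's title and the values show. The values are not scaled by gene length. Each of the 12 columns was matched by name to 1 sample, and 0 columns were left without a sample. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

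Every column consisted of multiples of a constant, the worth of 1 read, and in each library 100% of values were whole numbers of reads within a tolerance of 0.01. Read counts were recovered from this and summed to the depths in the text, from 58247 to 5839680 reads per library. The count of 0 in a library allows up to 3 reads, which are 37.3 normalised counts in YPG day 2 replicate 1 and 0.425 in YP day 9 replicate 1. Intervals and floors cover counting error only. Where a group had 0 reads for an ID, a lower bound on the fold was computed against 3 reads over the group, and with 1 to 3 reads the ratio of pooled reads is given with its exact 95% interval. No group's replicates were copies of 1 library, as chi-square per degree of freedom between replicates was 1.88 to 35.39.

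The main test was chosen before the data were examined. It was limma 3.58.1 (trended variance) in R 4.3.3 on log2 of the normalised value plus 5, over all 12 libraries in a layout of 6 groups with 6 residual degrees of freedom. IDs with a value of at least 10 in at least 2 libraries were kept, 5095 of 7376. Each of the 8 comparisons was adjusted over these IDs by the Benjamini-Hochberg method with a threshold of 0.05. Where counts of IDs with an unadjusted p under 0.05 are given, a share of 0.05 of the tested IDs is expected with no change. Because whole reads could be recovered, the quasi-likelihood test of edgeR 4.0.16 with TMM factors was run on them as a second test, with the Benjamini-Hochberg adjustment. It called 57, 544 and 1151 IDs for YP day 5 against 2, day 9 against 5 and day 9 against 2, 12, 66 and 439 for YPG day 4 against 2, day 7 against 4 and day 7 against 2, 236 between the media at day 2 and 626 for the time course difference. DESeq2 1.42.0 was also run on the recovered reads.

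Both tests were tested on simulated data with 200 IDs changed and the depths of these libraries. Counts were drawn once per comparison from edgeR's model with its dispersions, each ID on its own. The shares below may therefore favour edgeR and are not error rates of the real lists. In the YP comparisons of day 5 against 2, day 9 against 5 and day 9 against 2, 2.78%, 5.41% and 1.2% of limma's calls were false, and 8.53%, 12.1% and 9.49% of edgeR's. In the comparisons that hold YPG day 2, limma's false calls were 28.9% (YPG day 4 against 2), 32.8% (YPG day 7 against 2), 26.7% (media at day 2) and 10.2% (time course difference), where edgeR's were 4.82%, 4.69%, 1.37% and 3.28%. For YPG day 7 against 4 they were 5.1% and 9.4%. Counts from both tools are therefore given throughout. The steps ran on 4868 to 4901 IDs.

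The IDs did not match the reference table of 7443 genes by any of its identifiers (0 of 7376), so no names, products or coordinates are given. For the same reason the 32 gene lists fixed beforehand had no matched member, and no gene list test was run. The rule for named IDs, fixed beforehand, was the largest rises and falls in log2 fold change among called IDs whose replicates did not overlap between the groups and whose higher group mean was at least 50, limited without gene names to 2 that rose and 2 that fell per comparison. For the time course difference no separation of replicates was asked. The IDs vnz_13360, vnz_09725, vnz_19140 and vnz_37230 were chosen after their values were seen, as was the block of IDs without reads in YP replicate 1. Strand-specific libraries were made, but whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes may be mixed, as may reads of near-identical copies.

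Runs were stretches of at least 4 IDs next to each other in the table's ascending ID order that were all tested and called in the same direction. Their number was compared with 1000 shuffles of the calls over the tested IDs. Shuffling breaks up neighbours, so its p tests only whether calls cluster in ID order. The overlap of calls between media was compared with all 5095 circular shifts of one ordered list against the other, which keeps neighbouring IDs together. Alternatives tried were other pseudocounts, filters, scalings, library weights, sample sets and tools, reads thinned to the shallowest library, a replicate block and leaving out each library in turn. A library left alone in its group is then assumed to vary like the other groups.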

Results

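Gene expression was measured in cultures of Streptomyces venezuelae, a filamentous soil bacterium that forms spores and makes many specialised metabolites. The cultures were described as exploring, a mode of growth in which colonies spread rapidly over a solid surface. Cells were spotted on solid yeast extract-peptone medium without (YP) or with glycerol (YPG) and sampled 3 times on each. The YP groups were days 2, 5 and 9 and the YPG groups were days 2, 4 and 7, with 2 libraries in each of the 6 groups. Ribosomal RNA was depleted before a strand-specific library was made. The YP libraries were sequenced on a HiSeq and the YPG libraries on a MiSeq, so medium and sequencing platform cannot be told apart in any contrast between media. Only day 2 was sampled on both.

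The table held 7376 IDs and 12 libraries as DESeq2-normalised read counts. Total reads over all IDs ranged from 58247 in YPG day 2 replicate 1 to 5839680 in YP day 9 replicate 1. The other YPG totals were 114350 at day 2, 284874 and 363860 at day 4 and 901726 and 892570 at day 7. The other YP totals were 2044831 and 1125012 at day 2, 4855281 and 1108763 at day 5 and 2006464 at day 9. A single read therefore stood for 12.4 normalised counts in YPG day 2 replicate 1 and for 0.142 in YP day 9 replicate 1. In YPG day 2 replicate 1, 3202 of the 7376 IDs had no read. Replicates ranked the 5095 tested IDs with a Spearman correlation of 0.935 to 0.942 on YP, 0.933 at YPG day 4 and 0.955 at YPG day 7, but 0.84 at YPG day 2. These are correlations across IDs, which are not independent replicates. The first principal component held 38.8% of the variance and separated the media, with scores of -42.81 to -18.17 on YP and 20.22 to 44.41 on YPG.

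A pair of IDs took a large share of every library. The share of vnz_13360 was 17.1% ± 0.249 at YP day 2, 12.8% ± 1.2 at day 5 and 12.9% ± 0.576 at day 9 (SD, n = 2). On YPG it was 9.86% ± 0.256, 11.4% ± 0.573 and 18.7% ± 3.39 at days 2, 4 and 7. The share of vnz_09725 was 9.29% ± 2.7, 5.96% ± 1.3 and 4.82% ± 0.692 at YPG days 2, 4 and 7. On YP it was 3.63% ± 0.305, 2.77% ± 0.187 and 3.07% ± 0.19 at days 2, 5 and 9. Both were singled out after their values were seen.

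The last 154 IDs in ID order (positions 7223 to 7376) had 0 reads in all 3 YP replicate 1 libraries, out of 12739792 reads. In the other 9 libraries these IDs took 0.193% to 0.52% of reads, and 151 of them had a read in at least 1. For example, vnz_37230 had 158.2, 166.8 and 154.5 normalised counts in YP replicate 2 at days 2, 5 and 9 and 0 in replicate 1 at each of these times. It was chosen after its values were seen. A count of 0 allowed a share of up to 0.000147% at day 2, 6.18e-05% at day 5 and 5.14e-05% at day 9, for counting error only. Of the 154 IDs, 86 were tested, and between 0 and 1 of them were called in each of the 8 comparisons. Their means on YP average a replicate with reads and a replicate without, so their differences between media are not interpreted here.

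The files do not pair the IDs with gene names, so at most 2 IDs that rose and 2 that fell are printed per comparison. Groups of genes are described as runs, meaning at least 4 IDs that followed each other in ID order and were called in the same direction. Neighbouring IDs in bacteria are often cotranscribed. Values in the text are normalised read counts as mean ± SD over 2 libraries, and fold changes and adjusted p-values are from limma unless edgeR is named. The log2 values, and the rankings by them, are of the normalised value plus 5. This makes differences smaller where a group mean is low. For vnz_35035 on YP, day 9 against day 2, limma gave -5.45 and edgeR -6.88.

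The first comparisons asked how expression changed over time on YP. Between day 2 and day 5, 36 IDs were called, and 34 of these fell. The largest falls were in vnz_16915, from 369 ± 59.8 to 28.3 ± 11.5 (log2 fold change -3.52 ± 0.56 SE, adjusted p = 0.0164), and vnz_14975, from 1285 ± 163 to 126 ± 8.4 (-3.30 ± 0.24, adjusted p = 0.000101). The ID vnz_14975 belonged to a run of 5 that fell together by a median log2 of -2.95. The IDs that rose were vnz_09185, from 53.9 ± 39.4 to 270.6 ± 38.1 (2.40 ± 0.39, adjusted p = 0.0181), and vnz_25455, from 242 ± 21.5 to 708 ± 206 (1.50 ± 0.26, adjusted p = 0.0259). In all, limma called 36 of 5095 IDs, 2 higher and 34 lower, and edgeR called 57, 6 higher and 51 lower, among them all 36. DESeq2 called 173, 33 higher and 140 lower. An unadjusted p under 0.05 was found for 350 IDs, where a share of 0.05 of the 5095 is expected with no change. The count of 36 does not show that few IDs changed. On simulated data for this comparison limma recovered 1.49% of 2-fold and 40.3% of 4-fold changes. Among simulated IDs with a mean of 100 or more it recovered 5.88% of 2-fold and 95.5% of 4-fold changes. The limma count was 7 without YP day 5 replicate 2, 15 without YP day 5 replicate 1, 13 without YP day 2 replicate 1 and 22 without YPG day 4 replicate 2. The call of vnz_09185 was lost without YP day 2 replicate 1 (adjusted p = 0.0721), YP day 5 replicates 1 (0.0842) or 2 (0.241) or YPG day 4 replicates 1 (0.051) or 2 (0.0514), and that of vnz_25455 without YP day 2 replicates 1 (0.246) or 2 (0.0914), YP day 5 replicate 2 (0.332) or YPG day 4 replicates 1 (0.0551) or 2 (0.0557). That of vnz_16915 was lost without YP day 2 replicates 1 (0.0939) or 2 (0.0912) or YP day 5 replicates 1 (0.0621) or 2 (0.237). Without a filter on low values these 3 IDs had an adjusted p of 0.0737, and fitted to the 6 YP libraries alone vnz_09185 had 0.14 and vnz_25455 had 0.0894.

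Between day 5 and day 9 on YP, vnz_01075 rose from 101 ± 29 to 1444 ± 915 (log2 fold change 3.64 ± 0.38 SE, adjusted p = 0.00114) and vnz_01080 from 39.8 ± 6.04 to 563 ± 360 (3.51 ± 0.43, adjusted p = 0.0015). Both belonged to a run of 4 IDs that rose by a median log2 of 3.43. The largest falls were in vnz_07365, from 361 ± 172 to 15.1 ± 15.2 (-4.34 ± 0.50, adjusted p = 0.0015), and vnz_22100, from 266 ± 80.1 to 13.9 ± 18.1 (-4.25 ± 0.58, adjusted p = 0.00244). The run of 5 around vnz_14975 fell again, by log2 values of -2.46 to -1.63. In all, limma called 185 IDs, 64 higher and 121 lower, and edgeR called 544, 264 higher and 280 lower, among them all 185. DESeq2 called 815, 408 higher and 407 lower. The limma count was 23 without YP day 5 replicate 1, 115 without YP day 5 replicate 2, 35 without YP day 9 replicate 1, 118 without YPG day 4 replicate 1 or replicate 2, 332 without YPG day 2 replicate 1 and 331 without YPG day 2 replicate 2. Without YP day 9 replicate 2 the balance turned, to 114 higher and 100 lower. The call of vnz_22100 was lost without YP day 5 replicate 1 (adjusted p = 0.0561).

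Over the whole YP course, from day 2 to day 9, several sets of neighbouring IDs fell or rose together. The run of 6 that holds vnz_14975 (positions 2946 to 2951) fell by a median log2 of -4.75, and vnz_14975 itself went from 1285 ± 163 to 28.2 ± 8.79 (-5.30 ± 0.24 SE, adjusted p = 5.57e-07). The largest single fall was in vnz_35035, from 360 ± 58.8 to 3.47 ± 2.3 (-5.45 ± 0.48, adjusted p = 4.16e-05), where the day 9 mean rested on 25 reads. The largest rise was in vnz_08455, from 1.71 ± 2.42 to 134 ± 93.9 (4.23 ± 0.58, adjusted p = 0.000742), with 8 reads at day 2. The ratio of its pooled read counts was 76.2 (95% counting interval 38.6 to 177). The ID vnz_01075 rose from 71.2 ± 0.161 to 1444 ± 915 (4.09 ± 0.38, adjusted p = 5.82e-05), and its run of 4 (positions 208 to 211) rose by a median log2 of 3.74.

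Other runs on YP were 7 IDs that fell at positions 7188 to 7194 (median log2 -2.10), 4 that fell at positions 4697 to 4700 (-3.74) and 5 that rose at positions 5014 to 5018 (2.33). Altogether 94 of the 665 called IDs lay in 20 runs, 6 of IDs that rose and 14 of IDs that fell. With the calls shuffled over the tested IDs 1000 times, the mean number of runs was 0.132 and the highest was 2 (one-sided permutation p = 0.000999, the smallest that 1000 shuffles can give). This shows only that calls cluster in ID order, not that they are true changes, since neighbours may share noise. Of the 665 IDs that limma called, 270 rose and 395 fell, and edgeR called 1151, 552 higher and 599 lower. Both tools called 663 in the same direction. The limma count was 247 without YP day 2 replicate 1, 324 without YP day 2 replicate 2, 254 without YP day 9 replicate 1, 1012 without YPG day 2 replicate 1 and 1007 without YPG day 2 replicate 2.

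**Figure D1:**
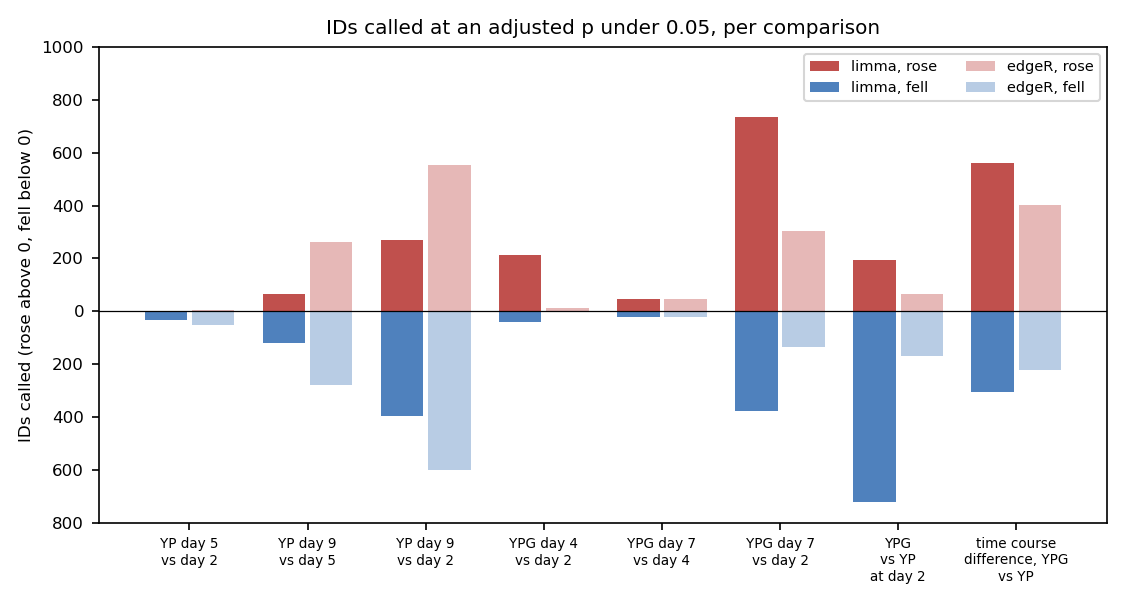
Number of IDs called at an adjusted p under 0.05 in each of the 8 comparisons, by limma (dark bars) and edgeR (pale bars). Bars above 0 are IDs that rose or were higher on YPG and bars below 0 are IDs that fell or were lower; limma called fewer than edgeR on YP (665 against 1151 for day 9 against day 2) and more on YPG where day 2 was involved (1113 against 439 for day 7 against day 2).

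The next comparisons asked how expression changed over time on YPG. Between day 2 and day 4, vnz_22555 rose from 12.6 ± 0.208 to 738 ± 82.5 (log2 fold change 5.40 ± 0.35 SE, adjusted p = 3.12e-05; edgeR adjusted p = 0.00329). Only 3 reads stood behind its day 2 mean, and the ratio of pooled counts was 57.9 (95% counting interval 19.7 to 282). The ID vnz_05735 had 0 reads at day 2 and 289 ± 5.84 normalised counts at day 4, at least 22.8-fold higher against a floor of 3 reads over the group. It was called by limma (adjusted p = 0.000981) but not by edgeR (adjusted p = 0.123), and it belonged to a run of 6 of which edgeR called 0. The largest falls were in vnz_10045, from 50.5 ± 18.6 to 11.1 ± 9.71 (-1.89 ± 0.49, adjusted p = 0.0493), and vnz_25225, from 59.8 ± 3.46 to 16.9 ± 8.84 (-1.63 ± 0.37, adjusted p = 0.0333). Neither was called by edgeR (adjusted p = 0.289 and 0.223), and 13 and 14 reads stood behind their day 2 means.

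In all, limma called 255 IDs from day 2 to day 4 on YPG, 214 higher and 41 lower, where edgeR called 12, all higher and all among the 255. DESeq2 called 65, 59 higher and 6 lower. With quantile normalisation limma called 114 higher and 59 lower. On simulated data drawn from edgeR's model, 28.9% of limma's calls and 4.82% of edgeR's calls in this comparison were false. Of limma's 41 false calls 34 were rises, and the count of 255 is not read as a count of changed IDs. The limma count was 10 without YPG day 4 replicate 1, 99 without YPG day 4 replicate 2 and 1228 without YPG day 2 replicate 2. It was 148 and 139 without YP day 2 replicates 1 and 2, 151 and 155 without YP day 5 replicates 1 and 2, and 161 and 166 without YP day 9 replicates 1 and 2. The call of vnz_25225 was lost without YPG day 4 replicates 1 (adjusted p = 0.0777) or 2 (0.134), YP day 2 replicates 1 (0.0617) or 2 (0.0622), YP day 5 replicates 1 (0.0575) or 2 (0.0565) or YP day 9 replicates 1 (0.052) or 2 (0.0518). That of vnz_10045 was kept only without YPG day 2 replicate 1, with adjusted p-values of 0.0586 to 0.204 without each of the other 11 libraries. It was also lost with a pseudocount of 1 (0.0709), no filter (0.0796), quantile normalisation (0.0508), library weights (0.401) and the 6 YPG libraries alone (0.215). The last 2 settings also ended the call of vnz_25225 (0.358 and 0.208), and library weights ended that of vnz_05735 (0.173).

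Between day 4 and day 7 on YPG, a run of 6 IDs (positions 5762 to 5767) rose by a median log2 of 3.54. Its members vnz_29245, from 55.4 ± 5.72 to 883 ± 427 (log2 fold change 3.79 ± 0.47 SE, adjusted p = 0.0044), and vnz_29270, from 88.1 ± 13.5 to 1382 ± 784 (3.78 ± 0.42, adjusted p = 0.00351), were the largest rises. The largest falls were in vnz_06995, from 150 ± 38.2 to 21.1 ± 8.2 (-2.59 ± 0.49, adjusted p = 0.0287), and vnz_01075, from 247 ± 40.8 to 47.3 ± 1.6 (-2.26 ± 0.38, adjusted p = 0.0161). In all, limma called 71 IDs, 48 higher and 23 lower, and edgeR called 66, 46 higher and 20 lower, with 57 called by both in the same direction. DESeq2 called 203, 111 higher and 92 lower, and with quantile normalisation limma called 55 higher and 41 lower.

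The limma count for day 7 against day 4 was 0 without YPG day 4 replicate 1, YPG day 4 replicate 2 or YPG day 7 replicate 2, with 610, 624 and 330 IDs at an unadjusted p under 0.05. Fitted to the 6 YPG libraries alone it was also 0, with 551 IDs at an unadjusted p under 0.05 and adjusted p-values of 0.0608 to 0.062 for the 4 named IDs. It was 113 without YPG day 7 replicate 1, 122 and 121 without YPG day 2 replicates 1 and 2, 37 and 36 without YP day 2 replicates 1 and 2, and 46 without YP day 5 replicate 1 or replicate 2. Without YPG day 4 replicate 1, YPG day 4 replicate 2 or YPG day 7 replicate 2, the adjusted p was 0.0909, 0.0681 and 0.0947 for vnz_29245, 0.0553, 0.0621 and 0.0672 for vnz_29270, 0.23, 0.158 and 0.211 for vnz_06995 and 0.113, 0.162 and 0.231 for vnz_01075. For vnz_06995 it was 0.0934 without YPG day 7 replicate 1 and 0.0624 with library weights. Without a filter on low values it was 0.0762 for vnz_06995 and 0.0514 for vnz_01075.

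Over the whole YPG course, from day 2 to day 7, a run of 5 neighbouring IDs (positions 2817 to 2821) rose by a median fitted log2 of 6.41. Its member vnz_14315 had 0 reads at day 2, 142 ± 0.71 normalised counts at day 4 and 1025 ± 497 at day 7, at least 78.6-fold higher than day 2 (adjusted p = 7.52e-07; edgeR adjusted p = 0.000104). The ID vnz_22555 rose from 12.6 ± 0.208 to 2581 ± 1220 (log2 fold change 7.12 ± 0.35 SE, adjusted p = 7.52e-07), a ratio of pooled counts of 198 (95% counting interval 67.7 to 961). The largest falls were in vnz_06995, from 506 ± 112 to 21.1 ± 8.2 (-4.31 ± 0.49, adjusted p = 0.000353), and vnz_20845, from 129 ± 29 to 14 ± 3.06 (-2.81 ± 0.38, adjusted p = 0.000801). Further runs that rose were 10 IDs at positions 5759 to 5768 (median log2 4.28, of which edgeR called 9), 6 at positions 1116 to 1121 (5.35, edgeR 5), 8 at positions 1492 to 1499 (2.15, edgeR 8) and 15 at positions 6840 to 6854 (1.75, edgeR 11). The medians of the runs at positions 2817 to 2821 and 1116 to 1121 include IDs with 0 reads at day 2, for which the fitted value depends on the pseudocount.

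Of 5095 IDs, limma called 1113 from day 2 to day 7 on YPG, 734 higher and 379 lower, and edgeR called 439, 304 higher and 135 lower. Both tools called 437 in the same direction. The median log2 fold change of all tested IDs was 0.199, and with quantile normalisation, which moved that median to -0.051, limma called 482 higher and 524 lower. With TMM factors limma called 743 higher and 369 lower, and DESeq2 called 519, 296 higher and 223 lower. On simulated data drawn from edgeR's model, 32.8% of limma's calls in this comparison and 4.69% of edgeR's calls were false. Of limma's 43 false calls 33 were rises. The 1113 calls held 21 runs, where 1000 shuffles gave a mean of 1.267 and at most 6 (one-sided permutation p = 0.000999, the smallest these can give), and edgeR's calls held 9 runs. The limma count was 251 without YPG day 7 replicate 2 and 1805 without YPG day 2 replicate 2.

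**Figure D2:**
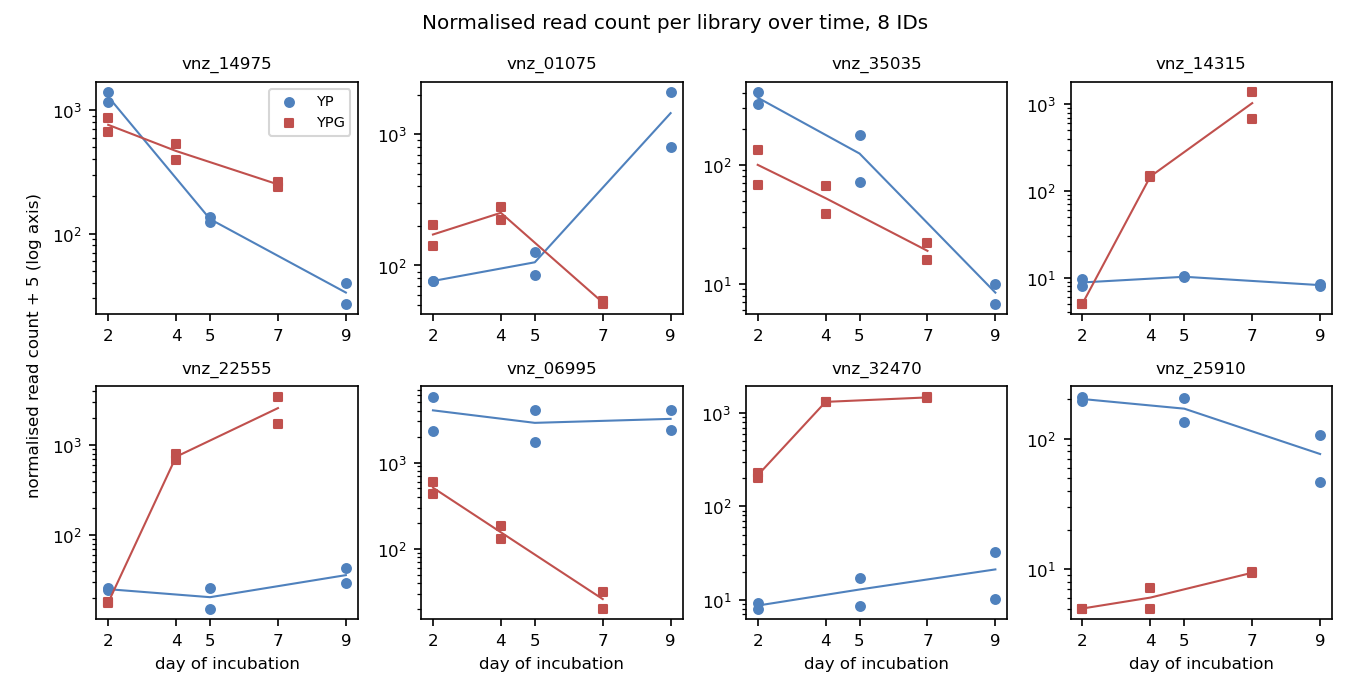
Normalised read count plus 5 (log axis) against the day of incubation for 8 IDs named in the text; each point is a library on YP (blue circles) or YPG (red squares), and lines join the group means. On YPG vnz_14315 and vnz_22555 climbed to means of 1025 and 2581 at day 7, on YP vnz_01075 reached 1444 at day 9, and vnz_06995 fell to 21.1 on YPG with a mean of 3208 at YP day 9.

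The comparison of the media at day 2 asked which IDs differed between YPG and YP at the time both shared. On YPG, vnz_32470 was higher at 211 ± 18.8 against 3.66 ± 0.858 (log2 difference 4.64 ± 0.46 SE, adjusted p = 0.000175), as was its neighbour vnz_32475 at 148 ± 2.01 against 3.45 ± 0.556 (4.18 ± 0.39, adjusted p = 0.000167). The run of 12 IDs at positions 6840 to 6851, which lies inside the run of 15 that rose over time on YPG, was higher on YPG by a median log2 of 2.20, and edgeR called 9 of the 12. The largest deficits were in vnz_05705, with 0 reads on YPG and 394 ± 434 normalised counts on YP, at least 24.3-fold lower on YPG (adjusted p = 0.000519; edgeR adjusted p = 0.0394), and vnz_25910, with 0 reads on YPG and 196 ± 10.8 on YP, at least 15.6-fold lower (adjusted p = 0.000129; edgeR adjusted p = 0.00658). The replicates of vnz_05705 on YP were far apart, as its SD shows, so its lower bound rests mainly on 1 of them. A run of 13 IDs at positions 4150 to 4162 was lower on YPG by a median log2 of -2.49, of which edgeR called 9. The median of their means at YPG day 2 was 12.6 normalised counts, the worth of 3 reads over the group. The size of this difference therefore rests on few reads and depends on the pseudocount.

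In all, limma called 917 IDs between the media at day 2, 194 higher on YPG and 723 lower, and edgeR called 236, 65 higher and 171 lower, of which 235 were called by both in the same direction. The median log2 difference of all tested IDs was -0.217. Quantile normalisation moved it to 0.07 and gave 356 higher and 433 lower, and DESeq2 called 119 higher and 219 lower. On simulated data drawn from edgeR's model, 26.7% of limma's calls and 1.37% of edgeR's calls were false. Of limma's 35 false calls 32 were lower on YPG. Fitted to the 4 day 2 libraries alone, limma called 0 IDs, with 1219 at an unadjusted p under 0.05 and adjusted p-values of 0.0629 for vnz_32470, vnz_32475 and vnz_25910 and 0.0728 for vnz_05705. The count was 219 without YP day 2 replicate 1, 410 without YP day 2 replicate 2 and 1667 without YPG day 2 replicate 2. Because the media were sequenced on different platforms, no within-platform value can be given.

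The last comparison tested whether the change from day 2 to the last day differed between the media, with 5 days on YPG set against 7 days on YP. A platform effect that adds a constant to the fitted log2 value of an ID cancels in it. One that multiplies the count is no such constant for IDs with few counts, because 5 was added before the log2. The rise in depth from day 2 to day 7 on YPG need not cancel either. The run of 4 that holds vnz_01075 and vnz_01085 (positions 208 to 211) rose on YP by a median log2 of 3.74, with all 4 called, and had a median of -1.73 on YPG, where 3 of 4 were called. On YP vnz_01085 rose from 114 ± 16 to 1712 ± 1050 and on YPG it fell from 251 ± 67.1 to 71.5 ± 25, a difference of -5.47 ± 0.58 SE (adjusted p = 0.000264). For vnz_01075 the difference was -5.79 ± 0.54 (adjusted p = 0.000139), from a rise of 4.09 on YP and a fall of -1.70 on YPG. The run of 5 at positions 2817 to 2821 had a median log2 fold change of 6.41 on YPG, where all 5 were called, and of 0.08 on YP, where 0 were called (median difference 6.14, 4 of 5 called by edgeR). For its members vnz_14315 and vnz_14300 the differences were 7.70 ± 0.52 (adjusted p = 2.84e-05) and 7.12 ± 0.57 (adjusted p = 5.78e-05), where vnz_14300 went from 0 reads at YPG day 2 to 683 ± 300 at day 7, at least 52.5-fold higher, and from 4.26 ± 0.619 to 3.82 ± 1.8 on YP. With reads thinned to the shallowest library, edgeR did not call the difference of vnz_14315 (adjusted p = 0.0783).

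The run of 6 that holds vnz_14975 fell on YP by a median log2 of -4.75, with all 6 called, and had a median of -0.75 on YPG, where 3 of 6 were called, and edgeR called the difference in all 6. A run of 8 at positions 4886 to 4893 had medians of 0.90 on YP and -1.12 on YPG, with 3 called on YP, 7 on YPG and 7 for the difference by edgeR. A run of 6 at positions 3501 to 3506 had medians of -1.53 on YP, all called, and 0.76 on YPG, where 1 was called, and edgeR called the difference in all 6. Of the 10 IDs at positions 5759 to 5768 that rose on YPG, 8 formed a run for the difference, with a median of 3.13, but edgeR called that difference in 1. The 8 had medians of 1.61 on YP, where 3 were called, and 4.68 on YPG, where all 8 were called. On YP edgeR called a run of 9 rises at positions 5759 to 5767.

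Of 5095 IDs, limma called the time course difference in 867, 562 more positive on YPG and 305 more negative, and edgeR in 626, 403 and 223. Both called 609 in the same direction. Among limma's 867, 305 had risen on YPG with no call on YP, 149 had fallen on YP with no call on YPG, 134 had fallen on YPG with no call on YP and 85 had risen on YP with no call on YPG. A further 43 had risen on YPG and fallen on YP, and 39 had fallen on YPG and risen on YP. The median difference of all tested IDs was 0.213, and quantile normalisation, which moved it to -0.024, gave 451 more positive and 467 more negative. The count was 391 without YP day 2 replicate 1, 488 without YP day 2 replicate 2, 510 without YP day 9 replicate 1, 372 without YPG day 7 replicate 2 and 1640 without YPG day 2 replicate 2, and it was 68 with days 4 and 5 in place of days 7 and 9, 66 more positive and 2 more negative.

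**Figure D3:**
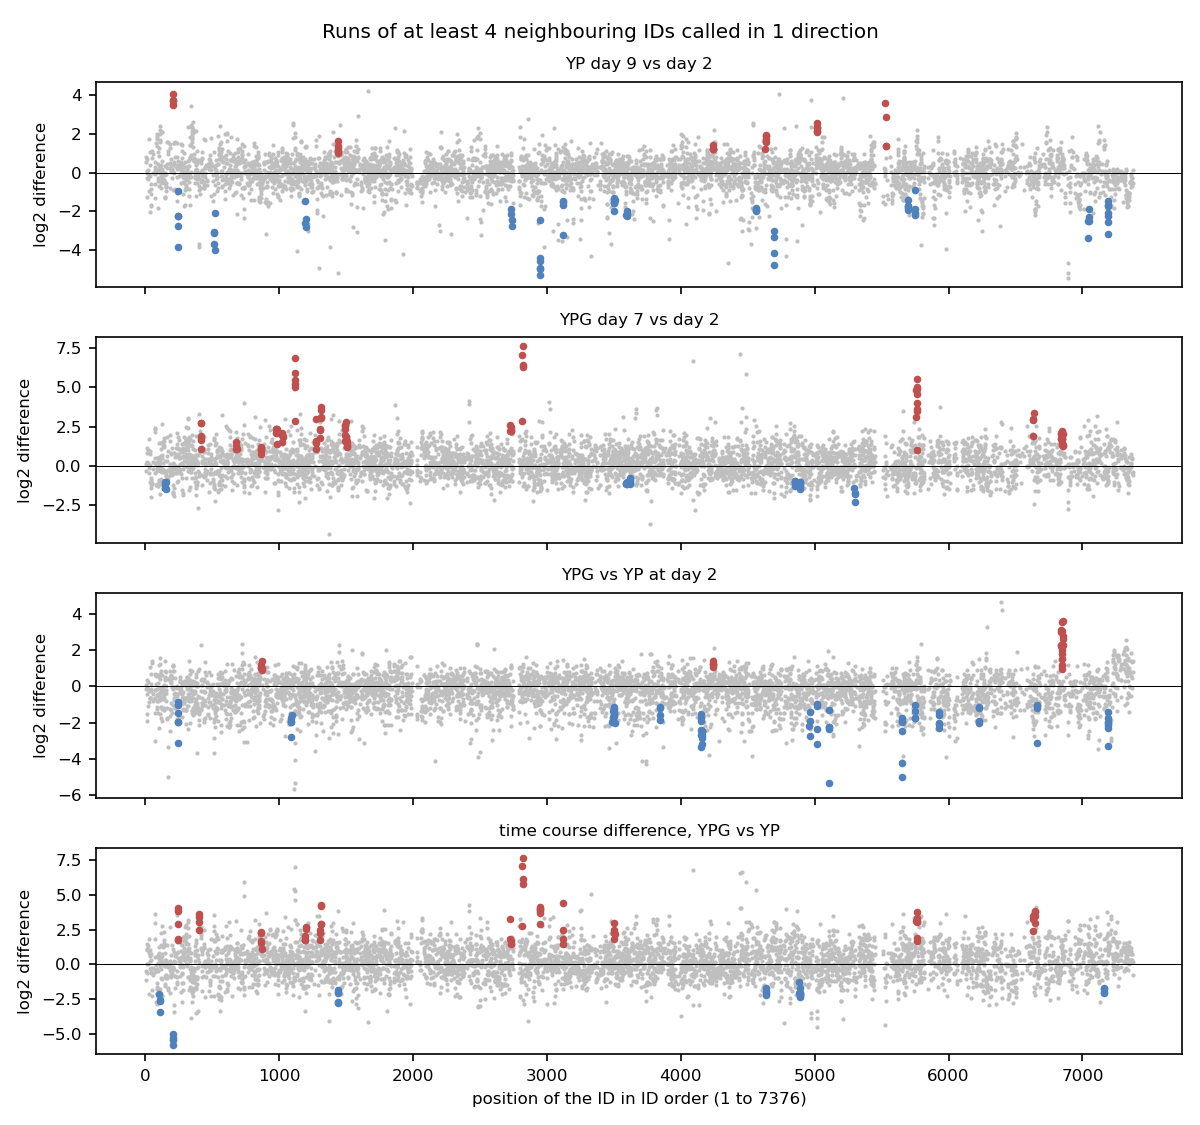
Log2 difference of every tested ID (grey) against its position in ID order, from 1 to 7376, in 4 comparisons. Coloured points are members of runs of at least 4 neighbouring IDs called in the same direction by limma (red higher, blue lower), which numbered 20, 21, 19 and 19 from top to bottom.

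The measured changes on the 2 media were weakly correlated across IDs. The log2 fold changes of YP day 9 against day 2 and YPG day 7 against day 2 share no library. Over 5095 IDs they had a Pearson correlation of 0.115 and a Spearman correlation of 0.055. The YPG day 2 libraries held only 58247 and 114350 reads, and their replicate Spearman correlation was 0.84. Counting noise lowers a correlation between fold changes, and no limit for it was computed. How closely the changes in the cultures were related therefore stays open. Of the IDs that limma called, 73 fell on both media, where independent lists would share 29.4 (exact circular shift test over 5095 shifts, two-sided p = 0.000196, the smallest it can give). The 47 that rose on both compared with 38.9 for independent lists (p = 0.174 by the same exact test), but by edgeR 61 rose on both against 32.9 (p = 0.000196). The 39 that rose on YP and fell on YPG compared with 20.1 (p = 0.000785 by the same exact test), and by edgeR 21 compared with 14.6 (p = 0.1). The opposite cell went the other way, with 43 that fell on YP and rose on YPG against 56.9 (p = 0.0591 by the same exact test). By edgeR it was 28 against 35.7 (p = 0.213 by the same exact test). Both of limma's lists took the variance of an ID from the same fit over all 12 libraries. IDs with little variance or many reads are therefore easier to call on both media. The shifts do not keep this, so an excess over independent lists does not by itself show a shared response.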

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

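The tests of the scaling and of the low depth of the YPG day 2 libraries were chosen after the values they use had been seen, while the test of a fixed platform offset was chosen before. The time course differed between the media, by limma's test of that difference, in 867 of 5095 IDs. By edgeR the difference was called in 626 IDs, and in 196 with reads thinned to the shallowest library. Among the named IDs of the whole time courses, vnz_14315, vnz_14300 and vnz_22555 rose more on YPG, with differences (YPG minus YP, log2) of 7.70, 7.12 and 6.62 ± 0.50 SE (adjusted p = 2.84e-05, 5.78e-05 and 4.81e-05). The first 2 of these had 0 reads at YPG day 2, so their fitted values are no bounds. The falls of vnz_14975 and vnz_35035 were steeper on YP, with differences of 3.71 ± 0.34 (adjusted p = 0.000128) and 3.11 ± 0.68 (adjusted p = 0.011). The IDs vnz_01075 and vnz_01085 rose on YP and fell on YPG, with differences of -5.79 and -5.47. The ID vnz_06995 fell on YPG, where its log2 fold change on YP was -0.23 (difference -4.08 ± 0.69, adjusted p = 0.00379). The ID vnz_08455 rose on YP, where its log2 fold change on YPG was 0.08 (difference -4.16 ± 0.82, adjusted p = 0.00744), but edgeR did not call that difference (adjusted p = 0.199). For vnz_20845, which fell by -2.81 on YPG and -1.28 on YP, the difference was not called (-1.53 ± 0.54, adjusted p = 0.0761).

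More IDs rose than fell from day 2 to day 7 on YPG, 734 against 379 by limma and 304 against 135 by edgeR. On simulated data 33 of limma's 43 false calls in this comparison were rises, and 1 of edgeR's 3. The few reads of the day 2 libraries stay open as a cause: with all 12 libraries thinned to the shallowest total, 62.2% of edgeR's 225 calls rose, but the 95% interval of a bootstrap over stretches of 20 neighbouring IDs ran from 52.3% to 71.7%. The scaling of the libraries stays open too. Other size factors kept the excess of rises, with 66.8% of limma's calls under TMM factors (743 against 369). Quantile normalisation gave 47.9%, but it forces all libraries to 1 distribution, so it tests more than size factors and cannot decide. A biological shift over time also stays open and was not tested apart from these.

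At day 2, 235 IDs were called between YPG and YP by both tools. Unequal depth of the media alone is argued against, since with all 12 libraries thinned to the shallowest total edgeR still called 166 IDs. That count was known when the test was chosen, and false calls of edgeR at the thinned depth were not simulated. If the sequencing platform added a fixed offset per ID, the media would differ as much later. Over the 235 IDs the later difference was a median of 0.641 of that at day 2 (95% bootstrap interval over IDs 0.55 to 0.743), with 1.25 for IDs higher on YPG and 0.507 for those lower. This ratio decides nothing, since a lasting effect of the medium can give any value and the choice of IDs called at day 2 pulls it below 1. Medium and platform cannot be told apart because each medium was sequenced on 1 platform.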

How the results depend on the processing

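The settings without both YPG day 2 libraries, without the block of 154 IDs, and with crossed numbers were chosen after seeing the data. The counts of called IDs depended strongly on tool, libraries and weights. A similar count under an alternative need not hold the same IDs. For YPG day 7 against day 2, quantile normalisation called 1006 IDs, of which 861 were among the 1113 of the main test. Of 849 values of the 32 named results under alternatives, 771 kept direction and side of the threshold, 78 kept direction but missed the threshold, 47 of them with 1 library left out, and 0 reversed. Reversals were largely excluded by construction, since most named IDs were chosen for replicates that did not overlap and many settings leave the fold change as it is. Unless the construction is named, the cause was not tested. Against main counts of 36, 185, 665, 255, 71, 1113, 917 and 867, in the order of the report, edgeR called 57, 544, 1151, 12, 66, 439, 236 and 626, and DESeq2 called 173, 815, 1390, 65, 203, 519, 338 and 738. In these counts IDs to which DESeq2 gave no adjusted p were kept as uncalled, up to 2865 of 5095 for YPG day 4 against day 2. Among the 849 values they were left out instead, so DESeq2 gave a value for 30 of the 32 named results. With arrayWeights the first 4 counts were 114, 583, 1480 and 4, and those of YPG day 7 against day 2, the media at day 2 and the time course difference were 161, 141 and 502. Fitted to the libraries of the medium or groups compared alone, with fewer samples, the counts were 12 (YP day 5 against 2), 1131 (YP day 9 against 2), 35, 0 and 403 (YPG day 4 against 2, 7 against 4, 7 against 2) and 0 (media at day 2). For both counts of 0, 551 and 1219 IDs had an unadjusted p under 0.05. With reads thinned to 58247 per library on average, edgeR called 280 (YP day 9 against 2), 44 (YPG day 4 against 2), 225 (YPG day 7 against 2), 166 (media) and 196 (difference), which is fewer than at full depth except for YPG day 4 against 2, where it called 12 at full depth. Without a filter the counts were 20 (YP day 5 against 2), 107 (YP day 9 against 5) and 46 (YPG day 7 against 4), with a minimum of 50 they were 59 (YP day 5 against 2) and 147 (YPG day 4 against 2), and with a pseudocount of 1 the count was 38 (YPG day 7 against 4). Quantile normalisation gave 293 for YP day 9 against 5, and days 4 and 5 in place of 7 and 9 gave 68 for the difference. Without both YPG day 2 libraries the counts were 36 (YP day 5 against 2), 332 (YP day 9 against 5), 1006 (YP day 9 against 2) and 122 (YPG day 7 against 4). Without the block of 154 IDs they were 36, 214, 689, 298, 74, 1167, 964 and 904. With 1 library left out the counts ranged over 7 to 46, 23 to 332, 247 to 1012, 10 to 1228, 0 to 122, 251 to 1805, 219 to 1667 and 372 to 1640 in the same order. A count of 0 came without YPG day 4 replicate 1, YPG day 4 replicate 2 or YPG day 7 replicate 2, where 610, 624 and 330 IDs had an unadjusted p under 0.05. The gene list settings (fry and an estimated correlation) were not run, since no list had a matched member. Depth limited YPG day 2 most, where 1 read stood for 12.4 and 6.37 normalised counts.

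With the replicate number within each medium as a replicate block, the counts were 41, 212, 679, 206, 74, 1155, 934 and 881. Of the 32 named results 31 kept their call, and vnz_10045 in YPG day 4 against day 2 had an adjusted p of 0.0659. Differences between replicates 1 and 2 correlated across IDs by 0.396 to 0.459 between the YP groups, and by 0.02 (days 2 and 4), 0.014 (days 2 and 7) and -0.151 (days 4 and 7) between the YPG groups. With the YPG day 4 numbers crossed, the replicate block gave 87 calls for YPG day 7 against day 4.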

Other observations

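The tests of a replicate number term, of the reads in the block and of the block's removal were chosen after the result was seen, and that of depth outside the block before its value was computed. Several sets of neighbouring IDs not described above changed on 1 or both media. A run of 4 IDs at positions 6645 to 6648 had a median log2 fold change of -1.99 on YP, where 2 were called, and of 1.61 on YPG, where 0 were called, and edgeR called the difference in all 4. The median of their means at YPG day 2 was 11 normalised counts, where 3 reads over the group stood for 12.6. A run of 5 at positions 1195 to 1199 had a median of -2.38 on YP, with 4 called, and had a median of 0.14 on YPG, with 2 called, and edgeR called the difference in 5. A run of 5 at positions 1437 to 1441 rose by a median of 1.26 on YP, with all 5 called, and had a median of -0.90 on YPG, with 4 called, and edgeR called the difference in 5.

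The ID vnz_19140, chosen after its values were seen, differed between replicates on YP, with 1036 and 6006 normalised counts at day 2, 247 and 5096 at day 5 and 143 and 1689 at day 9 in replicates 1 and 2. Its means on YP therefore average 2 replicates that are far apart, and no difference between media is read from it.

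Libraries with the same replicate number deviated together on YP, with correlations of 0.396 to 0.459 across IDs between the replicate differences of the 3 times. With the 154 IDs that had no reads in YP replicate 1 removed, the correlations were 0.087 to 0.203 with a mean of 0.152, but these IDs were picked for that deviation, so the drop had to follow and decides nothing. The higher depth of replicate 1 is argued against for the IDs outside the block. Their mean correlation was 0.13 (95% bootstrap interval over stretches of 20 IDs 0.095 to 0.167) with the YP libraries thinned to 1108763 reads on average. For the block, higher depth is argued against too. The 3 replicate 1 libraries had 0 of 12739792 reads there, and the 3 shallower YP replicate 2 libraries had 13044. More depth would add reads to these IDs, not remove them. The IDs were picked for 0 reads in replicate 1, but in the other 9 libraries they took 0.193% to 0.52% of reads. A term for the replicate number called 66 IDs over the 6 YP libraries, 60 of them in the block, which was picked for this deviation, and 6 outside it. What the libraries of 1 number shared stays open: a culture lineage without this DNA and counting against a sequence set without these IDs would each give 0 reads and cannot be told apart, because the labels describe neither, and no biological explanation was tested.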
